A study of Homo sapiens with 6 samples.

How the data were processed

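Accessibility was measured in 6 libraries of GM12878 cells: 2 from cells sorted for high H3K27ac, 2 from cells sorted for low H3K27ac and 2 from live, unsorted cells. Per the labels' protocols, cells were stained for viability, fixed with paraformaldehyde, stained for H3K27ac and sorted, and replicates of 50000 cells were transposed for 30 min at 37 °C. Crosslinks were reversed overnight before DNA was purified, except in the live control, where DNA was purified straight after transposition. The labels write the mark as H3K27ac, except the staining protocol, which gives the antibody target as H3K37ac and was read as H3K27ac. Each sample's group and replicate number came from its title.

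Per the submitters' processing notes, the processing used bcl2fastq, FastQC, Bowtie2, Picard and MACS2, with no versions given, and the builds hg38 and hg19. Aligner and caller settings, the shift for the Tn5 cut site, duplicate removal and the exclusion of problem regions are not given in the sources used here. Each deposited list holds single-base summits with a score, which was read as the −log10 of a q-value or p-value from the authors' peak caller. The lowest score in any list was 2.02. The score is the authors' own value for each summit and grows with a library's depth, so it was used to rank summits within a list and never compared between lists. Peaks were listed per library and not on pooled libraries, so each replicate has its own list. Contig names and positions past the ends of hg19 chromosomes show that the lists are on hg38, and all coordinates are given 1-based on that build. No read counts or signal were used here, so depth and its precision are unknown, and intervals on shares cover counting error only.

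Summits on chromosomes 1 to 22 and X from all 6 libraries that lay closer than 250 bp to the next were chained into 100513 regions (median width 43 bp). Each library's regions were ranked by their best score, ties being broken by a seeded draw, and the best 25627 kept, the number in the shortest list. The live control libraries had 69919 and 72284 regions, the high libraries 25627 and 46552, and the low libraries 41828 and 51754. No 2 of the lists were identical. Gene positions came from a RefSeq gene table for GRCh38.p14 with 19974 protein-coding genes on these chromosomes. The plan was to use transcript starts, but the table gives gene starts and ends without strand, so the distance to the nearer gene end was used. Among genes over 5000 bp with a summit of both live libraries at an end, 92.6% had it at 1 end only. A region was named by the protein-coding gene with the nearest end within 100 kb. A reference genome sequence was not used here, so 17 consensus motifs listed before the data were examined were not searched.

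The tests, the 18 gene lists (364 entries, of which 363 matched the gene table) and the rule for named regions were fixed before the data were examined. Values per library were compared with exact permutation tests, two-sided for differences and one-sided for overlap. With 2 libraries per group an exact permutation test cannot go below p = 0.333, and over 15 pairings or splits not below 0.0667. Sets of regions were compared with Fisher's exact test, with Benjamini-Hochberg adjustment over lists or chromosomes, beside the same value for the crossed pairs of the 4 sorted libraries. The lists are B cell identity, NF-kB and lymphoblastoid activation, plasma cell differentiation, early B progenitor, interferon response, MHC class I and II, histone acetylation regulators, Polycomb and DNA methylation regulators, cell cycle G2 and M, DNA replication and S phase, stress and heat shock, ribosomal proteins, housekeeping, T and NK cell markers, myeloid markers, erythroid and megakaryocyte markers, neural developmental genes and B lymphoblastic leukemia drivers. The counts of open genes, the share of each list open in all libraries, the breakdown by chromosome and the density correction were added after the data were seen. The named regions were the 12 high-only and 12 low-only regions, and the 8 sorted-only and 8 live-only regions, whose worse rank in the libraries that hold them was best, 1 per gene. Up to 4 members of each list with such a region at a gene end were added. The rule as fixed spoke of percentile ranks, and the ranks themselves were used.

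For values at equal gene density, regions were divided into 10 classes by the number of protein-coding genes within 500 kb, the nearest gene not counted, and class shares were weighted alike in every library. Labels were permuted within classes 100000 times. Alternatives covered list length, chaining distance, gene-end window, the rule for absence, the assignment of regions to genes, the replicate number as a block and each library left out.

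The region comparison was tested on simulated lists of the real lengths. In these, 200 regions were shifted between the sorted groups, some towards high-only and others towards low-only. The lists were made from 1 common ranking plus noise of the size seen between replicates, pooled over the 3 groups. At shifts of 1, 2 and 4 SD, 9.5%, 25% and 69% of the 200 regions came out in the right class, among 90636 to 90710 regions. With no shift, 3.5% of the 200 came out in that class by chance and 9 regions in the opposite one, and 1010 high-only and 994 low-only regions arose in all. The simulated gene-end share of high-only minus low-only regions moved from 2.85 points with no shift to -5.24 points at 4 SD. The shifted regions thus went in the direction of the reported gene-end difference. The recovered shares hold for these 200 regions and are no general sensitivity to a rise in 1 group. Scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.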

Results

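Chromatin accessibility was measured in GM12878, a B lymphoblastoid cell line immortalised by Epstein-Barr virus. Cells were fixed, stained for H3K27ac, a histone mark of active promoters and enhancers, and sorted into a population with high and a population with low staining. Each was then profiled with InTAC-seq, a form of ATAC-seq for fixed and stained cells, in which the transposase Tn5 places sequencing adapters in open DNA. Live, unsorted cells profiled without reversal of crosslinks served as the control. The 6 libraries fell into 3 groups of 2: H3K27ac high, H3K27ac low and live control. Per the labels, sorted cells were divided into replicates of 50000 cells, so the spread between replicates may be technical. The permutation tests between groups of libraries measure only that spread, and tests over regions or genes do not use it.

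The deposited data were 1 list of peak summits per library. The live control lists held 70100 and 72476 summits, the H3K27ac-high lists 25754 and 46708, and the H3K27ac-low lists 41980 and 51944. Means were 71288 ± 1680 (SD, n = 2) in the live control, 36231 ± 14817 (SD, n = 2) in the high and 46962 ± 7046 (SD, n = 2) in the low group. The lists give no read numbers, so the depth of each library is unknown. To compare lists of unequal length, summits on chromosomes 1 to 22 and X were joined into 100513 regions, and the 25627 best-scoring regions of each library were used. That number is the whole list of H3K27ac high replicate 1, the shortest. A region is said to lie at a gene end when its best summit was within 1 kb of either annotated end of a protein-coding gene, because the annotation used here gives no strand and so does not tell a start from a stop. A gene is called open in a library when 1 of the library's best regions lay at either of its ends.

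Genes of the cell cycle, DNA replication and ribosomal proteins were open in all libraries more often than the average gene, and genes of other lineages less often. Of 19974 protein-coding genes, 8063 (40.4%) were open in all 6 libraries. The genes of the G2 and M phases of the cell cycle were open in all 6 libraries for 18 of 20 members (Fisher's exact test against all protein-coding genes, adjusted over the lists alone, p = 5.37e-05), those of DNA replication and S phase for 19 of 22 (p = 7.03e-05) and those of ribosomal proteins for 22 of 26 (p = 5.37e-05). Housekeeping genes followed with 15 of 20 (exact p = 0.00581), regulators of histone acetylation with 16 of 23 (p = 0.0106), genes of NF-kB signalling and lymphoblastoid activation with 18 of 27 (p = 0.0167) and drivers of B lymphoblastic leukemia with 12 of 18 (p = 0.0442). None of 18 myeloid markers (exact p = 0.000538), none of 16 erythroid and megakaryocyte markers (p = 0.00119) and none of 16 neural developmental genes (p = 0.00119) was open in all 6 libraries, against 2 of 21 T and NK cell markers (p = 0.00692) and 2 of 16 genes of early B progenitors (p = 0.0366).

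The remaining 6 lists did not pass. Genes of B cell identity were open in all 6 libraries for 10 of 26 members (exact p = 1), Polycomb and DNA methylation regulators for 9 of 22 (p = 1) and genes of the interferon response for 10 of 20 (p = 0.557). Plasma cell genes stood at 9 of 13 (exact p = 0.059), MHC class I and II genes at 11 of 16 (p = 0.0521) and stress and heat shock genes at 14 of 23 (p = 0.0662). Counted by library, 12 (H3K27ac high replicate 1) to 17 (low replicate 2) of the 26 B cell identity genes were open. Over all 19974 genes that range was 8917 to 9914. An open site inside a gene, away from its annotated ends, does not count here. Genes are not independent replicates, and these tests describe the 6 lists. With the best 12813 regions of each list, the calls for NF-kB, histone acetylation, leukemia driver and early B progenitor genes were lost, leaving 4 lists above and 4 below. The calls for leukemia driver and early B progenitor genes were also lost with gene-end windows of 500 and 2500 bp, and that for NF-kB genes with 500 bp. Calls above the average gene were gained for plasma cell and stress genes with full lists, plasma cell and MHC genes with 500 bp, and MHC and stress genes with 2500 bp.

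The first comparison asked whether cells with high and with low H3K27ac differ in accessible chromatin. Regions at gene ends ranked higher in the H3K27ac-low than in the H3K27ac-high lists. Among the 25627 best regions, the share at gene ends was 31.8% and 33.1% in the high libraries, with a mean of 32.5% ± 0.94 (SD, n = 2), and 34.6% in both low libraries, with a mean of 34.6% ± 0.07 (SD, n = 2). The live controls lay between them at 33.9% and 33.7% (33.8% ± 0.10, SD, n = 2). The Wilson 95% intervals, which cover counting error only, ran from 31.2% to 33.7% over the high and from 34.0% to 35.2% over the low libraries. The difference of -2.12 percentage points was larger than the spread within either group, and the exact permutation test gave p = 0.333 (two-sided), the smallest that 2 libraries against 2 allow.

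The separation was wider at the top of the lists. Among the best 12813 regions, 43.0% and 47.1% lay at gene ends in the high libraries, 52.7% and 52.3% in the low libraries, and 48.5% and 47.9% in the live controls. Among the best 2500, an alternative chosen after the data were seen, the shares were 62.2% and 69.8% (high), 80.7% and 79.8% (low), and 68.3% and 68.2% (live). With full lists the direction turned, to 4.25 points higher in the high group, and at equal density of neighbouring genes the difference among the 25627 best regions shrank to -0.306 points, with both sorted groups above the live controls. Leaving out 1 sorted library at the same length gave -1.45 and -2.79 points without H3K27ac high replicates 1 and 2. Without low replicates 1 and 2 the difference was -2.07 and -2.17 points. With high replicate 1 left out and the lists also lengthened to 41828 regions, the next shortest length, it was -0.204 points.

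**Figure D1:**
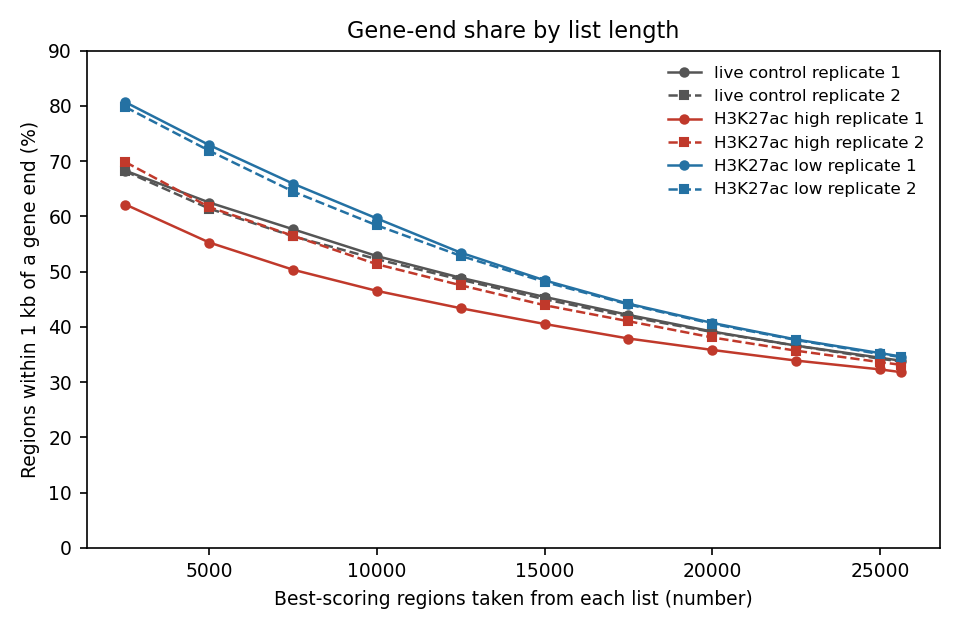
Share of regions within 1 kb of a protein-coding gene end (y axis, percent) among the best-scoring regions of each list (x axis, number of regions taken), with 1 line per library. At 2500 regions the low libraries stood at 80.7% and 79.8% and the others between 62.2% and 69.8%, and at 25627 regions all 6 lay between 31.8% and 34.6%.

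High-only regions, those in both high and neither low library, numbered 980, and low-only regions numbered 1364. Their sum of 2344 exceeded the 1637 and 1286 of the other 2 ways to divide the 4 sorted libraries into pairs. Simulated libraries with no difference between groups gave 1010 high-only and 994 low-only regions. That simulation gave all libraries 1 noise level, and the crossed pairs of the real libraries gave smaller sums (631 and 1006, 528 and 758). The simulated counts are therefore no chance level for these libraries. Low-only regions lay at a gene end in 25.1% of cases (343 regions), high-only regions in 12.2% (120 regions), a difference of -12.9 points (Fisher's exact test, two-sided, p = 3.05e-15). That test compares these libraries and not the conditions, since regions are not replicates. The same difference was 0.495 points (exact p = 0.75) and 3.31 points (p = 0.0858) in the crossed pairs. The median distance to the nearest gene end was 27464.5 bp for high-only and 11859.5 bp for low-only regions. At equal density of neighbouring genes the difference was -5.00 points (permutation test within density classes, p = 0.00756), with the best 12813 regions it was -46.9 points (Fisher's exact test, p = 4.89e-81), and with full lists it turned to 6.88 points. It was -6.19 points without H3K27ac low replicate 1 and -6.53 without low replicate 2. Without H3K27ac high replicates 1 and 2 it was -14.3 and -17.0 points. With high replicate 1 left out and the lists also lengthened to 41828 regions, the next shortest length, it was -4.14 points. Leaving out any 1 sorted library, which leaves fewer libraries to match, raised the high-only regions to between 1846 and 5500 and the low-only regions to between 2199 and 4069. With full lists, high-only and low-only regions numbered 445 and 3094. Without high replicate 1 and with the lists lengthened they numbered 6103 and 3375, so their balance depended on the setting.

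Most of these regions were also called, below the 25627 best, in at least 1 library of the other group. Of the 980 high-only regions, 832 were also called somewhere in the full list of a low library, and 100 more had a low summit within 1 kb. Of the 1364 low-only regions, 1127 were called in the full list of a high library and 81 had a high summit within 1 kb. The 25627 best regions are the whole list of H3K27ac high replicate 1, so every low-only region was absent from that library. Those 1127 were therefore called in high replicate 2 alone. That left 48 high-only and 156 low-only regions with no summit of the other group within 1 kb. Requiring presence in the best 12813 regions of one group and absence from the full lists of the other left 30 and 21 regions. With summits also joined up to 1000 bp, 0 and 1 were left.

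The best-ranked regions of both kinds lay at gene ends with a summit of the other group close by. All 24 regions that the naming rule took had such a summit within 1 kb, and 10 of the 12 high-only and 11 of the 12 low-only regions lay at a gene end. High-only regions with a low-only region within 1 kb numbered 32, and the same count was 26 and 13 in the crossed pairs of libraries. At PPAT, which encodes an enzyme of purine synthesis, the high libraries had their summit at chromosome 4, 56436047 to 56436128 (hg38), and the low libraries at 56435597 to 56435674. CSE1L, which encodes a nuclear export factor, had high summits at chromosome 20, 49046239 to 49046360, and low summits at 49046718 to 49046785. CLTRN, UTP18 and C10orf143 likewise appeared in both sets, as did IFI16, an interferon-induced DNA sensor, whose summits lay 21776 and 22066 bp from the nearest gene end. The adjoining ends of ELP2 and SLC39A6 on chromosome 18 held a high summit at 36129785 to 36129837 and a low one at 36129455 to 36129460. The other high-only regions of this set were at or near CDHR2, NFYC, SLC36A4, RASA2 and TMEM164. The other low-only regions were at SMDT1, MZF1, NAGLU, PNPLA2 and KEAP1, the gene of a sensor of oxidative stress.

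Joining summits up to 1000 bp, an alternative chosen after the data were seen, left 24465 best regions per library to compare. Then no gene was named in both sets, though all 8 high-only and all 8 low-only regions had a summit of the other group within 1 kb. The 8 best low-only regions then included the gene ends of KEAP1, FBL, TRIM25, HPS4, GNAZ and PACS1. FBL, which encodes the nucleolar protein fibrillarin, ranked 7938 and 5839 in the low libraries, 25287 in H3K27ac high replicate 2 and was absent from high replicate 1. The 8 best high-only regions were near CAPSL, GALNT13, ADM, BMP2K, CXADR, CBLB, PTTG1 and KLHL36, and the region at CAPSL was the one at a gene end. The region 42217 bp from an end of CBLB, a ubiquitin ligase of lymphocyte signalling, at chromosome 3, 105827232 to 105827260, ranked 10987 and 12216 in the high and 24595 and 29641 in the low libraries. Under this setting the difference in gene-end share was -18.6 points (Fisher's exact test, p = 4.04e-32).

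No fixed gene list separated high-only from low-only regions. Fisher's exact test on the 770 high-only and 1206 low-only regions within 100 kb of a gene end passed for 0 of 18 lists after adjustment over the lists alone (lowest p = 0.995) and for 0 at an unadjusted p under 0.05. B cell identity genes had 1 high-only and 10 low-only regions (exact unadjusted p = 0.0592), stress and heat shock genes 0 and 4, histone acetylation regulators 2 and 5, B lymphoblastic leukemia drivers 1 and 4, housekeeping genes 1 and 4, and NF-kB genes 4 and 4. Plasma cell genes had 0 and 3, MHC genes 0 and 3, Polycomb and DNA methylation regulators 2 and 3, and interferon response, G2 and M phase and ribosomal protein genes 0 and 2 each. Early B progenitor and S phase genes had 1 and 0 each, myeloid markers 0 and 1, and T and NK, erythroid and neural genes none. Without H3K27ac high replicate 1, 2 lists passed, B cell identity with 3 and 13 regions (exact test, adjusted p = 0.0372) and stress and heat shock with 0 and 8 (adjusted p = 0.0277). Without high replicate 2, 2 other lists passed, plasma cell genes with 2 and 14 regions (exact test, adjusted p = 0.0151) and MHC genes with 1 and 12 (adjusted p = 0.0151).

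Over all genes, 343 low-only and 120 high-only regions lay at gene ends. At the ends of the list genes, 12 of the named regions, up to 4 per list, were low-only and 4 high-only, a similar balance. The low-only regions included SPI1 and IRF8, transcription factors of the B cell and myeloid lineages. They also included the acetyltransferase genes EP300 and CREBBP and the Polycomb genes RING1 and CBX2. JUNB, MX2, HLA-C, RPL23 and EEF2 were among them too. The region at SPI1 (chromosome 11, 47378572 to 47378604) ranked 18127 and 18852 in the low libraries and 27432 in H3K27ac high replicate 2. The high-only regions were at CD58, TYMS, ACTB and the acetyltransferase gene KAT2B, and a low summit lay within 1 kb of each. Like every low-only region, all 12 had to be absent from high replicate 1, whose whole list is its 25627 best regions. Of the 12, 11 were present lower down in the list of high replicate 2. Of the 12 low-only and 4 high-only regions, 1 and 3 kept their kind with full lists, 2 and 0 with the best 12813 regions, and 7 and 0 with summits joined up to 1000 bp. Over all protein-coding genes, 293 were open in both low and no high library and 50 in both high and no low library. With full lists these were 191 and 10, and with the best 12813 regions 562 and 60. Among the 25627 best regions, high replicate 1 had the fewest open genes, 8917, against 9506 to 9914 in the other libraries. How far the balance rests on that library was not tested.

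The balance of low-only and high-only regions differed between chromosomes, a breakdown chosen after the data were seen. Chromosome 19 held 121 low-only and 7 high-only regions (Fisher's exact test, adjusted over 23 chromosomes, p = 4.72e-20), chromosome 17 held 101 and 16 (p = 2.18e-10) and chromosome 22 held 46 and 1 (p = 2.45e-09). Of the best regions, 4.3% and 4.0% lay on chromosome 19 in the live libraries. The high libraries had 3.0% and 3.6% there, and the low libraries 4.2% and 4.5%. On chromosomes 17 and 22, too, both high libraries lay below the live and the low libraries. The imbalance on these chromosomes therefore need not be a gain in the low cells. High-only regions took a larger share on chromosome 2, with 103 against 88 (exact p = 0.00312), and on chromosome 5, with 77 against 64 (p = 0.00752). On both, the high libraries had a larger share of their best regions than the live and the low libraries. In all, 9 of 23 chromosomes passed, against 3 and 0 in the crossed pairs of libraries, but 2 passed with full lists and 16 with the best 12813 regions. The chromosome tests compare these libraries and not the conditions, since regions are not replicates. Every low-only region was absent from H3K27ac high replicate 1, whose whole list was used. Whether gene density accounts for the balance by chromosome was not tested.

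**Figure D2:**
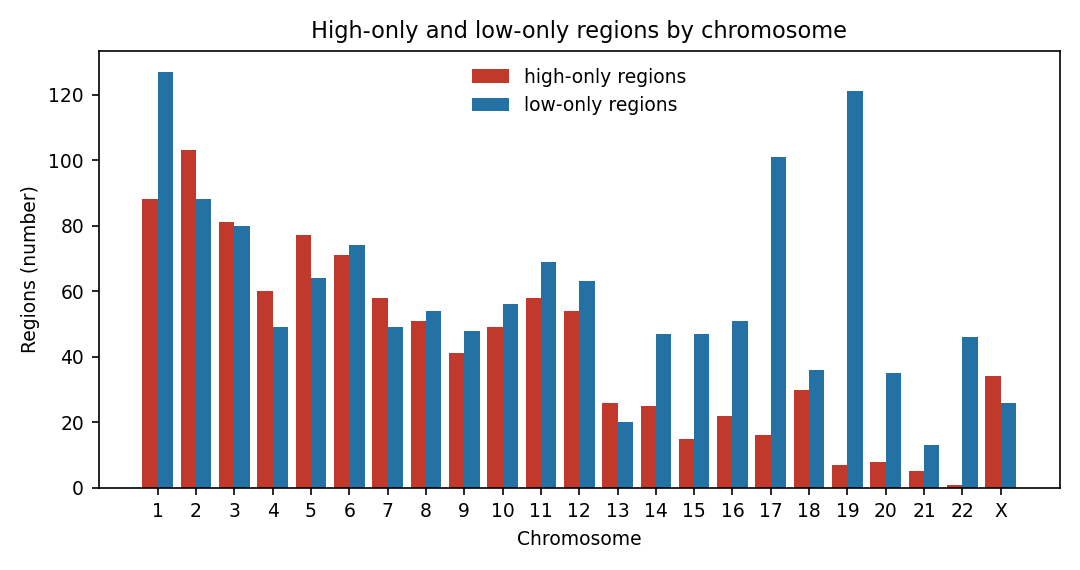
Number of high-only and low-only regions (y axis) on each chromosome (x axis), with 1 bar per kind. Chromosome 19 has 121 low-only and 7 high-only regions, while chromosome 2 has 88 and 103.

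The number of summits did not separate the sorted groups. The difference of means, high minus low, was -10731 summits, less than the range of the high pair (exact permutation test, two-sided, p = 0.667). Leaving out 1 sorted library at a time gave -254 and -21208 without H3K27ac high replicates 1 and 2, and -15713 and -5749 without low replicates 1 and 2.

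The second comparison asked whether libraries of a group resembled each other more than libraries of other groups. All 6 libraries shared 14593 of their 25627 best regions (56.9%), and 44.9% of the shared regions lay at gene ends. The Jaccard index, the shared share of the union, was 0.709 for the live pair, 0.707 for the low pair and 0.595 for the high pair. H3K27ac high replicate 2 overlapped the low libraries at 0.675 and 0.693, more than it overlapped high replicate 1. The mean within groups was 0.67 and between groups 0.622. Their difference of 0.0477 was the largest of the 15 ways to pair the libraries, the next being 0.0325 (exact permutation test, one-sided, p = 0.0667, the smallest possible). With full lists it was 0.0704 (exact p = 0.133), and leaving out 1 library gave 0.0260 to 0.107.

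**Figure D3:**
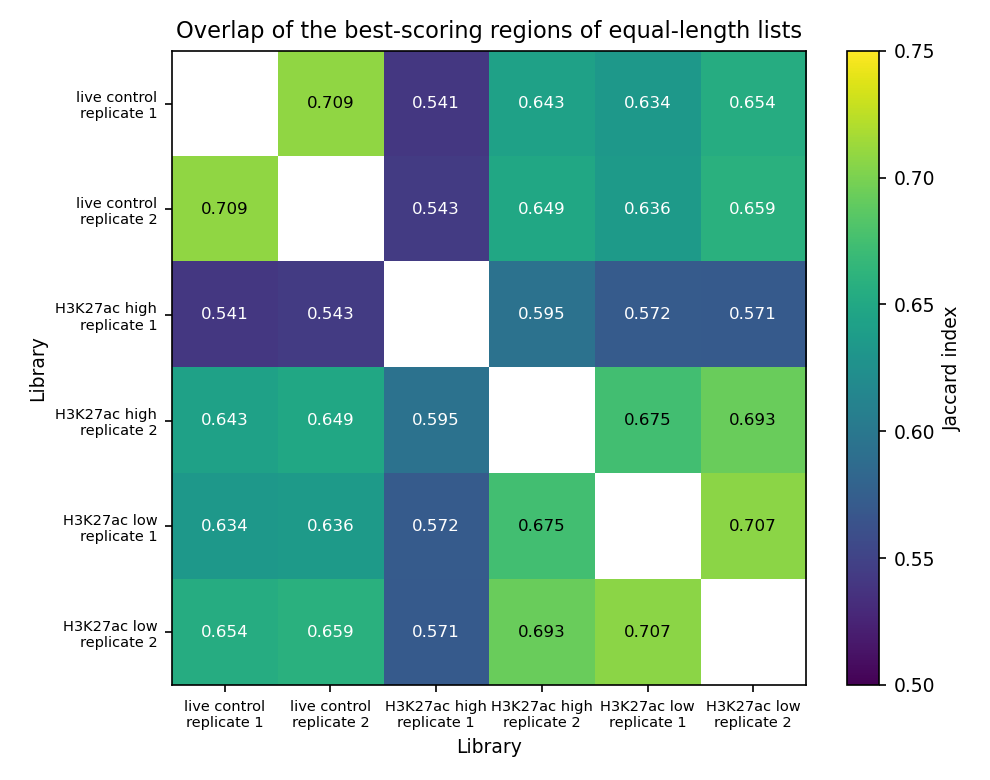
Jaccard index (colour and number) of the 25627 best regions for each pair of the 6 libraries, with a library on each axis. The live pair (0.709) and the low pair (0.707) overlap most, and H3K27ac high replicate 1 overlaps the others by 0.541 to 0.595.

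The third comparison set the 4 fixed and sorted libraries against the 2 live controls, which differ from them in fixation, staining, sorting and crosslink reversal together. Live-only regions, in both live and no sorted library, numbered 902, and 587 sorted-only regions were in all 4 sorted and neither live library. The highest numbers among the other 14 ways to divide the libraries 4 against 2 were 504 and 470, so both were the largest of 15 (exact share 0.0667, the smallest possible). With fewer libraries to match, live-only regions numbered 2428 and 2306 and sorted-only regions 1164 and 1150 without live control replicate 2 or 1, and sorted-only regions numbered 968 without H3K27ac high replicate 1. With full lists, whose lengths differ, live-only and sorted-only regions numbered 8405 and 155. Sorted-only regions lay at a gene end in 21.3% and live-only regions in 13.2% of cases, and 7 of the other 14 splits had a larger difference in that direction. The gene-end share of the 25627 best regions was not separated, at -0.272 points for sorted minus live (exact permutation test, two-sided, p = 0.933). Its sign turned under alternatives, to 7.72 points with full lists, 4.90 with the best 2500 regions, 0.803 at equal gene density, 0.533 with the best 12813 regions and 0.304 without H3K27ac high replicate 1.

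Here too the best-ranked regions lay close to a summit of the other side. At SP4, which encodes a zinc finger transcription factor, the sorted libraries had their summit at chromosome 7, 21427259 to 21427299, with ranks from 142 to 737, and the live libraries at 21428056 to 21428065, with ranks 2156 and 2575. ZBTB37 and NMT2 also appeared in both sets. The other sorted-only regions were at or near FMC1, SEH1L, ZFPM1, KLHL24 and STAM2, and the other live-only regions at or near PI4KA, KGD4, GSTA4, TMEM267 and PIWIL4. A summit of the other side lay within 1 kb of 7 of the 8 sorted-only and all 8 live-only regions. With summits joined up to 1000 bp, 6 of the 8 best sorted-only regions lay at gene ends, among them NFE2L2, which encodes a regulator of the oxidative stress response, and the RNA polymerase subunit gene POLR2J. None of the 8 best live-only regions did, among them regions inside MYH9, FOXK2 and AGAP3. Counted anew under that setting, live-only regions numbered 729 and sorted-only regions 494. Of the 8 live-only and 8 sorted-only regions named first, 0 and 0 kept their kind.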

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

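The gene-end share of high minus low, its list lengths and the count of splits were planned, and the other tests in this part were chosen after the results were seen. The gene-end share of the 25627 best regions moved in opposite directions from the live control in the sorted groups: -1.33 points in H3K27ac high, with both libraries below both controls, and 0.788 points in H3K27ac low, with both above. The gap between these shifts is the high minus low difference of -2.12 points (exact permutation test, p = 0.333). Each shift alone also gave p = 0.333 (exact permutation test), the smallest possible. Among the best 2500 regions, high replicate 2 (69.8%) lay above both controls (68.3% and 68.2%). The controls also differ from both sorted groups in fixation, staining, sorting and crosslink reversal. At equal gene density the high (32.9% and 32.3%) and the low libraries (33.3% and 32.6%) all lay above the controls (31.98% and 31.95%).

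The pattern weighed first is the lower gene-end share in the high than in the low lists. Among the 25627 best regions, giving every library the same gene-density make-up left -0.306 of the -2.12 points, with high replicate 1 (32.9%) above low replicate 2 (32.6%), so a smaller number of regions in gene-dense parts of the genome may account for most of it. Among the best 12813 regions the correction left -4.36 of -7.47 points, with both high libraries (45.4% and 47.3%) under both low libraries (51.1% and 50.2%), which argues against gene density as the whole cause there. List length stays open: high replicate 2, whose list length lies between those of the low lists, differed from the lower low library by -5.18 points (range of the low pair 0.437), but it is 1 library and read depth is unknown. Whether the H3K27ac level of the cells or a bias by base composition lies behind the rest was not tested.

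The second pattern is the larger number of regions set apart by the live control. Summits shifted within shared peaks were more numerous there, with 49 pairs within 1 kb against at most 14 in the other splits. The live split also had more regions that could pair, 902 live-only and 587 sorted-only. The split with 14 pairs, live control replicate 1 and H3K27ac high replicate 1 against the rest, had 233 and 313. The larger number of pairs therefore does not show that shifted summits were more frequent per region. If shifted summits were the whole cause, joining summits up to 1000 bp would bring the number of live-only regions near the other splits. Counted anew under that setting, it was 729 against at most 434. Of the 8 named live-only regions 0 kept their kind there, and how many of the 902 did was not counted. Of the 15 splits, 1 had as many live-only regions, the real one (902 against at most 504), and 15 splits are too few for a share under 0.05. Fixation, staining, sorting and crosslink reversal go together in this design and stay open.

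The third pattern is the turn of the gene-end share to 4.25 points higher in the high group with full lists. Over the 6 full lists the share fell as the number of regions rose (Spearman's rho = -1, permutation p = 0.00278; Pearson's r = -0.981, permutation p = 0.00139), and r was -0.994 without the 2 libraries farthest from the median length. List length is therefore a likely cause, since at equal length the sign was negative. No biological explanation was tested.

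DNA of 2 kinds outside the comparisons gave more summits in a sorted library than in either control. On the Epstein-Barr virus genome, H3K27ac low replicate 2 had 18 summits, against 16 and 17 in the live controls, 11 and 10 in the high libraries and 15 in low replicate 1. On contigs outside the main chromosomes the low libraries had 77 and 80 summits, against 63 and 67 in the live controls and 62 and 65 in the high libraries.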

How the results depend on the processing

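Of 119 values of the compared results under an alternative, 83 kept their direction or lay within 1.5 times the reported count. The side of the 0.05 threshold was required only for the gene-end share of high-only minus low-only regions. A kept direction was counted whatever its size, so the 83 include high minus low at -0.306 points at equal gene density, against -2.12. Joining summits up to 1000 bp, the best 2500 regions, equal gene density and the joint changes were chosen after the data were seen. Chaining distances of 100 and 500 bp and gene-end windows of 500 and 2500 bp gave only such values.

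With full lists, whose lengths differ, the gene-end share turned to 4.25 points (high minus low) and 7.72 points (sorted minus live), and that of high-only minus low-only regions to 6.88 points (Fisher's exact test, p = 0.000132). High-only, low-only, sorted-only and live-only regions then numbered 445, 3094, 155 and 8405. With the best 12813 regions, high-only, low-only and live-only regions numbered 631, 869 and 558, as shorter lists allow. The gene-end share of sorted minus live turned to 0.533 points there, to 4.90 points with the best 2500 regions and to 0.803 points at equal gene density. The cause was not tested for these 3 turns.

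Requiring presence in the best 12813 regions and absence from the other group's full lists left 30 high-only and 21 low-only regions, whose gene-end shares differed by -25.7 points (Fisher's exact test, p = 0.0642), with few regions left to test. With summits also joined up to 1000 bp, 0 and 1 regions were left and no share could be compared. Without H3K27ac high replicate 1 and with the next shortest list setting the length, high-only and low-only regions numbered 6103 and 3375 and the gene-end share of high minus low was -0.204 points and that of high-only minus low-only regions -4.14 points. At equal gene density the share of high minus low was -0.306 points.

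Leaving out 1 library at a time gave 1846 to 5500 high-only, 2199 to 4069 low-only, 795 to 1164 sorted-only and 1151 to 2428 live-only regions, as fewer libraries had to match. The gene-end share of sorted minus live ranged from -0.642 to 0.304 points, and 0 to 2 gene lists passed.

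Replicate numbers are shared between groups, and the labels do not say whether libraries of 1 number were prepared together. The correlation of replicate differences was 0.0328 between high and low, so no strong shared replicate effect was seen. That value cannot tell how the libraries were prepared. With the replicate number as a block the summit difference was -10731 and the gene-end difference -2.12 points (exact sign-flip test, p = 0.5 for each). That is the smallest p that 2 pairs of libraries allow, so this test could not separate the groups.

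Of the 12 high-only and 12 low-only named regions, 2 and 2 kept their kind with 500 bp chaining, and 0 and 1 with 1000 bp. Of the 12 low-only and 4 high-only regions at list genes, 11 and 1 kept theirs with 500 bp, and none with the best 12813 regions set against full lists. Motif tests and their alternatives were not run, since no genome sequence was used here. Depth is unknown, and regions low in a list or missing from it may be missing for depth alone: 832 of 980 high-only regions were called in a full low list, and 30 met the stricter rule.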

Other observations

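Epstein-Barr virus DNA, which GM12878 carries, had open sites in every library. Summits joined up to 1000 bp formed 17 sites on the viral sequence, of which 6 were present in all 6 libraries and 3 in 1 library. The shared sites, in the coordinates of the viral contig, were 6002 to 6609, 10482 to 11184, 35576 to 38152, 138278 to 139438, 165905 to 166418 and 169177 to 169484. At the site from 165905 to 166418, the best summit lay between 166413 and 166418 in the live libraries and H3K27ac high replicate 1, and between 165905 and 165941 in high replicate 2 and both low libraries. The site from 115085 to 115140 was called in both live libraries and low replicate 2, and in no high library.

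Open chromatin at long genes was mostly at 1 end. Of the genes over 5000 bp with a summit of both live libraries within 1 kb of an end, 9551 had it at 1 end and 758 at both.

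Of the regions with no summit of the other group within 1 kb, 2.08% of the 48 high-only and 15.4% of the 156 low-only regions lay at a gene end, against 59% and 49.4% of those with a shifted summit.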
